A study of Bos taurus with 9 samples.

How the data were processed

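The transcriptome of intercaruncular endometrium, the glandular part of the bovine uterine lining between the attachment sites of the placenta, was measured by RNA sequencing in 9 samples, 4 labelled normal and 5 labelled infectious. Per the labels' protocols, total RNA was extracted from frozen tissue with TRIzol and its quality was read on a Bioanalyzer before library preparation with standard Illumina protocols. The submitters' processing notes name HISAT2, SAMtools, HTSeq and DESeq2 and the genome build ARS-UCD1.2. Versions, the annotation release and the strand setting of the read counting are not given in the sources used here. The labels give no batch, day, animal history or pathogen for any sample. Nothing in them says in words that each sample came from its own animal, so the spread behind the p-values may be partly technical. That spread was also estimated in part from libraries outside these 9 samples, as described below.

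The values come from 1 table, the authors' own DESeq2 comparison of the infected with the control (normal) group, with 21696 Ensembl gene identifiers. The table holds 0 columns of values per sample. The baseMean column is a signal value that the authors computed, the mean over libraries of gene counts divided by DESeq2 size factors. The deposited fold changes and their standard errors are on the log2 scale, infected over control, and are not shrunken. The deposited test statistic is a Wald score, the log2 fold change divided by its standard error. The deposited p-value is the 2-sided normal p of that score, and the deposited adjusted p-value is its Benjamini-Hochberg adjustment from the authors' DESeq2 run. Recomputed from the score, the p-values differed from the deposited ones by at most 2.78e-15. Recomputed over the 17448 genes that carry an adjusted p, the adjusted values differed by at most 2.16e-15. A p-value was present for 21234 genes and missing for 462, although these carry a fold change, a standard error and a score. The DESeq2 run of the authors leaves the p-value empty in this way where a single library, of any group in the fit, holds an outlying count by Cook's distance. A further 3786 genes had a p-value and no adjusted p, and their means reached at most 1.19, just under the lowest mean with an adjusted p of 1.195. These are the genes that the independent filtering of low means by the authors' DESeq2 run left out.

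The design fixed before the data were examined gave a test for raw counts, for normalized values per sample and for a comparison table alone. The last case applied, so no model was refitted and the authors' adjusted p under 0.05 was counted as deposited. Levels per group, their SDs, leaving out single samples, other splits of the samples and other normalizations of the reads could not be computed from this table. The table does not pair its identifiers with gene names. The reference table of 37063 genes at hand (assembly ARS-UCD2.0) has 0 rows with an Ensembl identifier, so 0 of the identifiers matched a symbol. The 34 gene lists fixed beforehand (leukocyte, epithelial, stromal and other cell type markers, cytokines, antimicrobial proteins, interferon-stimulated genes, matrix, steroid and prostaglandin genes and others) could therefore not be applied, and 0 of them were tested. The rule for named genes required a symbol. In its place, 2 identifiers per direction are printed by parts of that rule without the symbol: the gene with the largest fold change among those past the threshold with a mean of at least 50, and the gene with the smallest adjusted p.

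The total reads per library are unknown. Relative depth was recovered from the lowest means. A gene with 1 read in 1 library has a mean equal to the inverse of the number of libraries times that library's size factor, so such genes share exact values, called steps here. Values under 0.1 shared by at least 3 genes were taken as steps. A gene was called private to a library if its mean was a whole multiple of that library's step, from 1 to 1000 reads, within 1e-09 of a whole number. Genes with reads in exactly 2 libraries were solved for both read numbers at means under 10, within 1e-10. In a simulation of 14 libraries with known size factors, the method found 14 of 14 steps, all 602 private genes with 0 false calls, and 517 of 517 genes with reads in 2 libraries. In the authors' table, 14 steps were found, 5 with positive, 4 with negative and 5 with zero fold change. The first 2 numbers match the 5 infected and 4 normal samples, which also fixes the sign of the fold change as infected over normal. The other 5 steps are libraries that entered the authors' fit and belong to neither group. They are not analysed here. The deposited mean is thus a mean over 14 libraries, as the geometric mean of the size factors also shows (1.01 at 14 libraries, against 1.57 if 9 are assumed), and the dispersion estimates behind the standard errors draw on all of them. Steps cannot be tied to individual samples, so libraries are named by their group and size factor.

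Shares are given with exact (Clopper-Pearson) 95% intervals, which cover counting error only, and genes are not independent of each other. The adjustment and the threshold were tested on simulated data, 17448 genes with the deposited standard errors, of which 200 were given a change. At an adjusted p under 0.05, 8.00% of the 50 genes changed by 1.5-fold, 20.0% of the 50 changed by 2-fold, 68.0% of the 50 changed by 4-fold and 66.0% of the 50 changed by 8-fold were called, and 3 of the 84 calls were unchanged genes. The authors' table has 2253 called genes. With so few changed genes the simulated adjustment was stricter, so these rates are not the detection rates of that table. The alternatives run on the counts of changed genes were adjusted p thresholds of 0.01 and 0.1, a minimum absolute log2 fold change of 1, a test against a fold of at most 1.5, a minimum mean of 10, Benjamini-Hochberg and Bonferroni adjustment over all genes with a p-value, an empirical null, and centring on the median gene. A minimum mean of 50 and p-values computed for the genes without one were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.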

Results

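Gene expression in the intercaruncular endometrium was compared between 5 samples from infected and 4 samples from normal bovine uterine tracts. The question set by the design was which genes differ in expression between the infected and the normal uterus. Expression was available as the authors' deposited table of fold changes for 21696 genes, of which 17448 had an adjusted p and were counted as tested. The size factors recovered for the 9 libraries ranged from 0.777 to 1.12, a 1.44-fold range in effective depth. Their median was 1.013 in the infected and 0.9998 in the normal group. For 665 genes the table lists a fold change of exactly 0 with a p-value of 1.

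In the authors' deposited table, 2253 genes differed between infected and normal endometrium at a DESeq2 adjusted p under 0.05, which is 12.9% of the genes tested. Expression was higher in infected endometrium for 1192 genes and lower for 1061, a balance that depended on the setting. It turned to 1068 higher and 1199 lower when the fold changes were centred on the median gene, and to 22 and 61 under an empirical null. With the genes without a p-value included, it was 1402 higher and 1096 lower. The added genes were left without a p-value for an outlying count, so their direction may rest on a single library. The higher genes had a median log2 fold change of 1.83, with quartiles of 1.22 and 2.84. The lower genes had a median of -1.61, with quartiles of -2.65 and -1.0004. On the linear scale these medians are a 3.54-fold increase and a 3.05-fold decrease. Among these genes, which were tested against no change, the estimated change was at least 2-fold for 1030 higher and 796 lower genes, at least 4-fold for 538 and 416, and at least 16-fold for 140 and 110. Tested against a change of at most 1.5-fold, 239 higher and 268 lower genes passed. The table pairs no identifier with a gene name, so the pathways and cell types behind these genes are not described here.

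**Figure D1:**
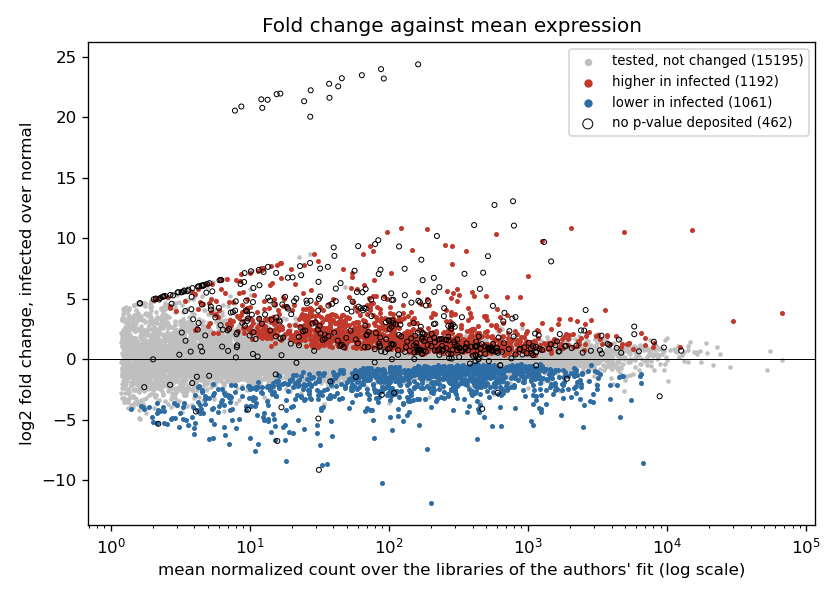
Log2 fold change of each gene, infected over normal, against its mean normalized count over the libraries of the authors' fit (log axis). Red points are the 1192 genes higher and blue points the 1061 genes lower at an adjusted p under 0.05, grey points are tested genes that did not pass, and open circles are the 462 genes without a p-value, of which 431 lie above 0.

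The gene with the largest increase among called genes with a mean of at least 50 was ENSBTAG00000017305. In the authors' deposited table its log2 fold change was 10.86 with a standard error of 2.07 (DESeq2 adjusted p = 1.23e-05) at a mean normalized count of 122. This gene did not pass under an empirical null. The increase with the smallest adjusted p was that of ENSBTAG00000048135. The authors' deposited table gives it a log2 fold change of 9.79 with a standard error of 0.86 (DESeq2 adjusted p = 5.15e-26) and a mean of 1269. Among called genes with a mean of at least 50, the largest decrease belonged to ENSBTAG00000052892, whose log2 fold change in the authors' deposited table was -11.85 with a standard error of 1.04 (DESeq2 adjusted p = 2.61e-26) at a mean of 202. The decrease with the smallest adjusted p was that of ENSBTAG00000002962. Its log2 fold change in the authors' deposited table was -2.27 with a standard error of 0.19 (DESeq2 adjusted p = 1.48e-29), a 4.81-fold decrease with a 95% interval of 3.73-fold to 6.21-fold, at a mean of 1449. Group levels are not part of the table, so the first 3 of these values, all beyond 9 on the log2 scale, cannot be separated from a fold against a group with few or no reads and are not given on the linear scale.

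The balance of increases and decreases differed with expression level. Among changed genes with a mean normalized count under 200, 761 were higher and 520 lower, so that 59.4% were higher (95% interval 56.7% to 62.1%). Among those with a mean of 200 or more, 431 were higher and 541 lower, so that 44.3% were higher (41.2% to 47.5%). Increases made up the largest share of changed genes, 66.2%, at means of 10 to 50, where 314 genes were higher and 160 lower. At means of 1000 and over, 92 were higher and 132 lower. The lowest class, from 1.195 to 10, departed from this order with 66 higher and 91 lower genes. Centring the fold changes on the median tested gene, which lay at 0.06 on the log2 scale, gave 695 higher and 566 lower genes under a mean of 200 and 373 and 633 at 200 or more. All of these counts leave out the 462 genes without a p-value. Most of those had positive fold changes at every level, 108 of 116 at means of 200 to 1000.

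**Figure D2:**
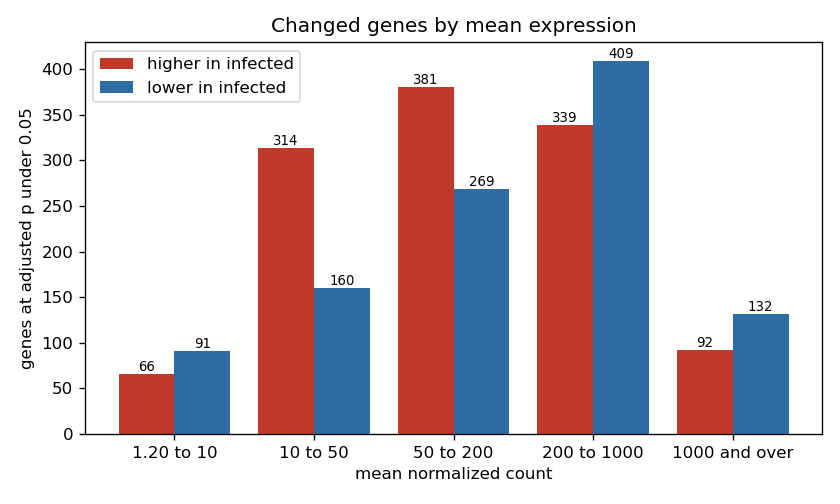
Number of genes at an adjusted p under 0.05 (y axis) in 5 classes of mean normalized count (x axis), higher in infected in red and lower in infected in blue. Higher genes outnumber lower ones at means of 10 to 50 (314 against 160) and 50 to 200 (381 against 269), and lower genes outnumber higher ones at 200 to 1000 (409 against 339) and at 1000 and over (132 against 92).

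The precision of the table differed with expression level. The smallest absolute Wald score among the called genes was 2.72. At the median standard error of genes with means of 200 to 1000, 0.31 on the log2 scale, this corresponds to a 1.81-fold change. At means of 10 to 50, with a median standard error of 0.62, a 3.204-fold change was needed, and at means under 10 an 8.61-fold change. These limits hold for a gene with the median standard error of its class, and more precisely measured genes passed at smaller changes, down to an absolute log2 fold change of 0.35. Of the tested genes, 4472 had an unadjusted p under 0.05.

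The 462 genes without a p-value stood apart from the tested genes in direction. Of these genes, 431 had a higher and 30 a lower expression estimate in infected endometrium, and 1 was listed at 0. The share with a positive fold change was 93.3% (95% interval 90.6% to 95.4%), against 53.3% among genes with a p-value above the same minimum mean. Their median log2 fold change was 2.09. The direction was alike at every expression level, with 82 of 91 genes positive at means under 10 and 44 of 47 at means of 1000 and over. The 18 genes with a log2 fold change over 20 were all among them, and 0 genes in the table fell below -20. Fitted values of this size carry no interpretable fold. None of these 462 genes is counted among the 2253. Of them, 162 had an absolute score at or above the smallest score of a called gene. All 462 lack a p-value because a library held an outlying count, so their fold changes and scores may rest on a single library. These scores are therefore not read as further changed genes.

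One infected library differed from the other 8 in how its reads were spread over rare genes. In the library with the lowest size factor, 0.777, 56 genes were private, that is, had reads in no other library of the authors' fit. Only 5 of these 56 genes, 8.93% (95% interval 2.96% to 19.6%), had a single read. In the other 8 libraries the number of private genes with a single read ranged from 45 to 71, and their share from 50.9% to 74.7%. The same infected library had 21 private genes with 10 or more reads, and its private genes held a median of 7 and a mean of 34.0 reads. The mean rested on 3 genes with more than 50 reads and was 8.96 reads without them, against at most 3.02 in the other 8 libraries under the same limit. A second infected library, with a size factor of 1.01, had 7 private genes with 10 or more reads and a mean of 4.52 reads. The 4 normal libraries together had 1 such gene. The counts of changed genes could not be repeated without these libraries, because the table holds no values per sample.

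**Figure D3:**
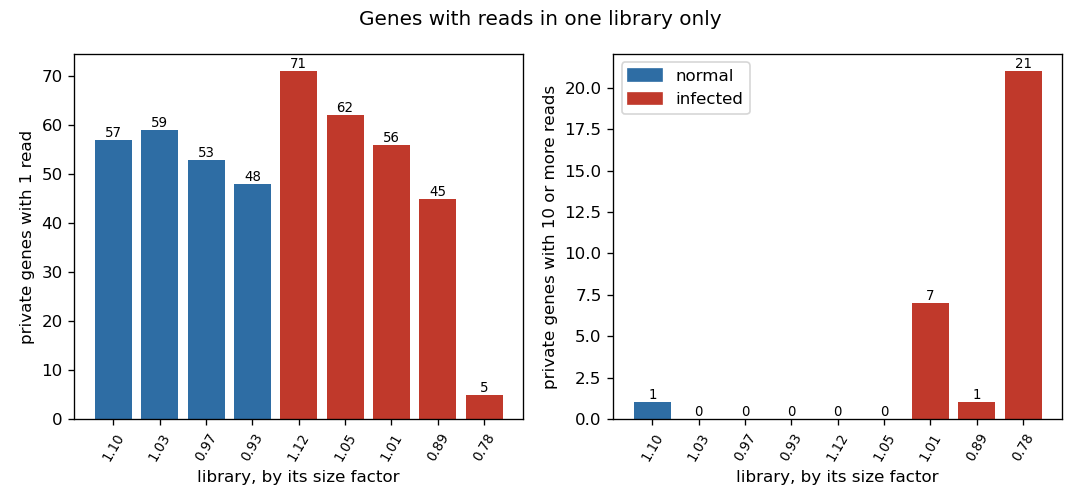
Number of genes with reads in 1 library only, for the 4 normal (blue) and 5 infected (red) libraries, each named by its DESeq2 size factor (x axis). The left panel counts private genes with 1 read and the right panel those with 10 or more. The infected library with a size factor of 0.78 has 5 and 21, while the other libraries have 45 to 71 and at most 7.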

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

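Of the tests in this part, the assignment of outlying genes to libraries and the check on genes with reads in 2 libraries had their predictions written before the result was seen. The others were chosen after it. In the search for samples far from their group, 14 sets of library values were tested, of which 3 passed the criterion, 1 of them by construction, and chance gives about 5% of such sets. Most of the sets rest on the same private genes, so they are not independent of each other.

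The first pattern is the 431 genes without a p-value that were higher in the infected group, a signal in rows that the count of changed genes leaves out. Outlying high counts spread at random over the 9 libraries would put about 55.6% of these genes higher. The observed 93.3% (lower bound 90.6%) argues against that. This reference places every outlying count in the 9 libraries, although it can also lie in a library outside the contrast. Reads could be assigned for 25 genes with reads in only 1 or 2 of the 9 libraries, and for these a single infected library is argued against: 48.0% (95% interval 27.8% to 68.7%) had most reads in the library with the lowest size factor, 12 genes in that library, 12 in the infected library with a size factor of 1.01 and 1 in a normal library. The other 437 genes were not assigned, among them nearly all of the 371 with a mean of at least 10. Of these 437, 6 had reads in 1 or 2 libraries, at least 1 of them outside the contrast, and the rest were not solved. A single library stays open for the 437 genes. Uneven disease between infected animals stays open as the biological explanation, since 0 severity records per animal were among the values used.

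The second pattern is the infected library with a size factor of 0.777, which stood far from the other 4 in its mean of 34.0 reads per private gene (median 7, and a mean of 8.96 without the 3 genes over 50 reads) and in the share of single reads among genes found in exactly 2 libraries, 7.14%. Its number and share of single-read private genes and its number with 10 or more reads did not meet the criterion. Their gaps to the nearest library, over the range of the group, were 0.606, 0.638 and 0.667 against a critical value of 0.71. A merely shallower library was predicted to keep single reads above 50% of its private genes. They made up 8.93%, with an upper bound of 19.6%, so the prediction was not met. RNA from another cell type added to the sample was predicted to leave the number of single-read genes in place. That was not met either, with 5 found against at least 45 in the other infected libraries. Both predictions were written after the result and read the values that define the pattern, so they are no separate tests. How far added RNA would lower the number of single-read genes was not measured, so added RNA stays open. Low library complexity, in which few molecules are each read several times, predicts the low share in genes found in exactly 2 libraries (7.14% of 56 genes, 95% interval 1.98% to 17.3%, against 54.1% to 72.7% in the other 8 libraries), but any cause that removes single reads from the whole library would give it too, so low complexity stays open and is not singled out. The origin of the 21 private genes with 10 or more reads cannot be told apart between added cell types and repeated reads, because none of them could be named.

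Among the 4 normal libraries, 1 had 1 private gene of 10 or more reads, a gene with 34 reads, against 0 in the others. A single gene against counts of 0 meets the criterion by construction and does not show that this library stands apart.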

How the results depend on the processing

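The settings on genes without a p-value, on private genes and on a minimum mean of 50 were chosen after seeing the data. The number of changed genes depended on the threshold and on the null distribution more than on filtering. Against 2253 genes (1192 higher, 1061 lower), an adjusted p under 0.01 kept 1257 (635 higher, 622 lower), a test against a fold change of at most 1.5 gave 507 (239 and 268), and Bonferroni adjustment gave 350 (128 and 222). An empirical null, scaled by the robust SD of the score of 1.69, gave 83 (22 and 61). These settings are stricter by construction, and the empirical null would take any real changes into its spread. The other 7 settings gave between 1721 and 3172 genes, all within 1.5 times the first count, with 2498 when the genes without a p-value were included. Higher genes were 36.6% of the Bonferroni calls and 26.5% under the empirical null, against 52.9%. Their share was 56.1% with the genes without a p-value included and 56.4% at a minimum absolute log2 fold change of 1. Under the remaining settings it lay between 47.1% (centring on the median gene) and 54.9% (adjusted p under 0.1). Of the 4 printed genes, which were picked for a small adjusted p or a large fold change, ENSBTAG00000017305 did not pass under the empirical null. Their fold changes move only under centring, so the other settings say nothing about their direction. The share of genes without a p-value that were higher was 94.1% at a mean of at least 10. With private genes limited to 50 reads, the mean in the library with the lowest size factor was 8.96 reads, against at most 3.02 in the other 8, so the height of that mean rests on a few genes with more reads. Not run, because the table has no values per sample or no gene names, were DESeq2 or edgeR fits, other size factors, pseudocounts, leaving out samples, other splits of the samples, and all gene list settings. Whether the count could arise from another grouping of the samples was therefore not tested. Depth in total reads is unknown, and at means of 200 to 1000 a gene with the median standard error needed a 1.81-fold change.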

Other observations

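The deposited p-values of the 17448 tested genes corresponded to an estimated 61.5% of genes without a change (Storey's estimate at a lambda of 0.5), so more genes may differ than the 12.9% called, or the scores may be spread too widely for the assumed null. Widening the null to the robust spread of the scores left 83 genes.

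The test in this paragraph had its prediction written before its result was seen, after the counts by threshold were known. Under Bonferroni adjustment, with genes of every mean counted, fewer genes were higher than lower (128 against 222). At an adjusted p under 0.05 the counts over every mean were 1192 higher and 1061 lower. With a mean of at least 50 they were evenly divided (812 against 810), a set that the Bonferroni counts were not limited to. A hypothesis was that genes higher in infected endometrium vary more between libraries, and so reach lower scores at the same fold change. Among 1763 genes with a mean of at least 50 and an absolute log2 fold change from 1 to below 3, within 11 strata of fold change and mean, the standard errors of higher genes were 0.960 times those of lower genes (95% bootstrap interval 0.919 to 1.02, from 1000 draws). The hypothesis was not borne out for these standard errors. They draw on all 14 libraries of the authors' fit, so they do not give the spread within the infected group. The comparison leaves out genes with means under 50, genes with an absolute log2 fold change of 3 or more, and the 462 genes without a p-value, of which most were higher. It therefore does not cover increases among these genes.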
